A study of Drosophila melanogaster with 2 samples.

How the data were processed

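The data were 2 biological replicates of ChIP-seq with an antibody against GFP on whole transgenic Drosophila melanogaster embryos aged 8 to 24 hours that carried a dati-eGFP fusion gene, per the labels. The age is that of the source name, because a separate age field holds a number of hours that no embryo reaches. Chromatin was fragmented by sonication with a labelled size range of 200 to 800. There was 1 group, so no groups were compared and no block or pairing applied.

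The authors deposited peak lists on build dm6, per the labels. The documentation deposited with each library names an alignment file of the replicate and 1 control alignment file, shared by both replicates, as the sources of the peaks. The aligner, the peak caller and their versions are not given in the sources used here. Ranked lists held 107484 places for replicate 1, 122195 for replicate 2, 156658 for the pooled reads and 151702 for the list that pairs both replicates. Thresholded sets were deposited for each replicate alone, for the pooled list (called optimal here) and for the paired list (called conservative here).

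The signal value of each peak is the authors' own, taken from their caller with the control as background, on a scale that is not given in the sources used here. It was used to describe and rank peaks within a list, and between replicates only as a correlation, a ratio or values side by side. The deposited score of each peak is the IDR on a scaled negative log2, with an upper limit of 1000: 100% of the scores of the pooled ranked list lay within 1 of that value. The IDR itself is held in the deposited ranked lists as a −log10 value. Another deposited column gives the summit as an offset in bp from the start of the peak, per the documentation's file type. The largest IDR in the optimal set was 0.0100, its lowest score 830, and 48, 65, 89 and 69 places at that score or higher in the lists of replicate 1, replicate 2, the pooled and the paired data were absent from the matching set. The documentation names a further source file for the thresholded sets, whose content was not used here.

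The depth of the libraries is unknown, because the lists hold no read counts. Precision is therefore given as exact binomial intervals (Clopper-Pearson, 95%) on numbers of peaks and as the spread of shifted peaks, and both cover counting error only. Paired columns of the series-level ranked lists carry no replicate name and were not used.

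Coordinates are given from 1 on build dm6. Genes came from the Ensembl annotation of the same assembly, without transposable elements, and sequence from the matching Release 6 assembly. Peaks outside arms 2L, 2R, 3L, 3R, X and chromosome 4 were left out of the tests. A summit was a promoter summit within 500 bp of any annotated start site, and otherwise took the first of 5' untranslated region, coding exon, 3' untranslated region, other exon, intron and intergenic that applied. Overlaps (at least 1 bp, one-sided) and location (two-sided) were tested against 100000 circular shifts along each arm. Counts per arm were tested with an exact binomial test against arm length.

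A gene was called bound with a summit within 1000 bp of an annotated start site. The 16 gene lists covered pan-neuronal, neuroblast and proneural, neuronal identity, axon guidance, glial, muscle and mesoderm, epidermis and trachea, gut with fat body and hemocyte, Hox, segmentation, Notch pathway, sex determination and courtship, heat shock, ribosomal protein, histone and chromosome 4 genes. They were tested with two-sided Fisher's exact tests against all 13945 protein-coding genes of the 6 arms. Of the listed names, 7 were not matched to a protein-coding gene and were not used here. Motifs (16, on either strand) and all 6-mers were compared between 101 bp windows at the summits and windows 500 bp to each side with two-sided Fisher's exact tests; 6-mers were found on 2L, 2R, X and 4 and tested on 3L and 3R. The matched control took 2 windows per peak of the same GC content, to 1 base, and the same class of distance to a start site. P-values were adjusted by the Benjamini-Hochberg method within each family (7 location classes, 6 arms, 16 lists, 16 motifs, and the 6-mers), with a threshold of 0.05.

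Lists, motifs, tests, the rule for named genes and all but 2 alternatives were fixed before the data were examined. The rule took the protein-coding gene with the nearest start site for the 20 optimal peaks of highest signal, up to 4 bound genes of highest signal per list, dati, and the 5 peaks with the largest difference in rank share between the replicates among the 200 highest. The alternatives tried were the conservative set, the 946 optimal peaks of highest signal, each replicate's own set, merging of overlapping peaks, other overlap rules, other promoter and binding distances, the nearest start site, gene spans, local shifts of at most 100000 bp, other window sizes, matched lists and windows, and other expectations per arm. The 2 added after the data were seen took HisRS out of the histone list, and added to the 1892 optimal peaks the places of the pooled ranked list on the 6 arms that reached the lowest score of that set, 1953 in all.

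The tests were tested on simulated data. With 1892 peaks scattered at random, 4.29% of location tests passed an unadjusted 0.05, and 5 of 100 simulations called any arm. With 30% of the peaks placed on start sites, the promoter excess found was 25.9 percentage points, against 26.0 implied. With 400 shared peaks planted among 859, 401 were found. A planted motif in 5% of 1892 windows was found with an excess of 5.02 percentage points, and 0 of 16 motifs were called without it. Over 100 simulations with random bound genes among 13945, each with 16 lists, 1 list was called in all. The simulated genes were drawn independently, so this leaves out neighbouring genes that share a peak. A bound share of 25% was called in 84 of 100 simulations for the 92 ribosomal protein genes. Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.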

Results

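Chromatin immunoprecipitation and sequencing (ChIP-seq) measured where a fusion of the Dati protein with enhanced green fluorescent protein (eGFP) sat on the genome of Drosophila melanogaster embryos aged 8 to 24 hours. The gene dati (datilografo, FBgn0262636) encodes a zinc finger protein and lies on chromosome 4, at 375640 to 395605 on the minus strand of build dm6. Chromatin of whole transgenic embryos was sheared by sonication to a labelled size range of 200 to 800, and the fusion protein was precipitated with an antibody against GFP. There was 1 group with 2 biological replicates and no second condition. The comparisons the design gives are therefore the replicates with each other and the peaks with the annotated genome. The peak lists hold no read counts, so the depth of each library is unknown, and the intervals given for shares of peaks are exact (Clopper-Pearson) 95% binomial intervals that cover counting error only.

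Replicate 1 had 1208 peaks past the deposited threshold on the irreproducible discovery rate (IDR), a measure of how well ranks of peaks repeat, and replicate 2 had 877, a ratio of 1.38. The set called optimal here, thresholded over both replicates, held 1915 peaks, and the conservative set held 1675, a ratio of 1.14. Of the optimal peaks, 1513 were also in the conservative set. The arms 2L, 2R, 3L, 3R, X and chromosome 4 carried 1892 of the optimal peaks, which are the ones described here. The median width of an optimal peak was 264 bp, which is also the largest width in the set, so it does not measure the breadth of binding. The median of the authors' signal value was 78.6.

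Most of the highest signals of the optimal set lay at promoters. The peak of highest signal, 936.2, was at 3L 19590507 to 19590713, with its summit 90 bp upstream of CG14100 (FBgn0036889). The next, with a signal of 928.8, was at X 2703788 to 2703999, 38 bp upstream of Ugalt (FBgn0024994), a UDP-galactose transporter gene. CG7601 followed with 696.2, and ph-p, a Polycomb group gene, with 666.4, its summit at X 2137340. Of the 20 highest peaks, 16 were at promoters (within 500 bp of an annotated transcription start site), 2 in introns and 2 between genes. The summit lay upstream of the nearest protein-coding start site in 15 of them.

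The other promoter peaks among these 20 named Tcs5 (signal 645.2), CenG1A (644.3), px (622.0), Art3 (621.3), mRpL41 (611.8), eIF6 (545.1), CG5611 (530.4), CG18549 (528.3), PNPase (515.8), Chro (480.5), CG1888 (476.0) and tank (460.4). Art3 encodes an arginine methyltransferase, mRpL41 a protein of the mitochondrial ribosome, eIF6 a translation initiation factor and PNPase a polynucleotide phosphorylase. Chro encodes Chromator, a chromatin protein of interbands. The intronic peaks were in CG11050 (2L 6612616 to 6612806, signal 607.4) and in Tlk, which encodes Tousled-like kinase (X 3742125 to 3742289, signal 478.1). The intergenic peaks were 3169 bp upstream of tara (3R 16222408 to 16222578, signal 534.7) and 11907 bp downstream of the start site of CG13323 (signal 559.0). A start site of another gene lay within 1000 bp in 11 of the 20.

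The first comparison asked how far the replicates' own peak sets shared places. On the 6 arms, 679 of 859 peaks of replicate 2 overlapped a peak of replicate 1 by at least 1 bp, a share of 79.0% (95% interval 76.2 to 81.7). In the other direction 679 of 1201 peaks of replicate 1, or 56.5% (53.7 to 59.4), overlapped a peak of replicate 2. After circular shifts along the arms the mean shares were 0.426% and 0.305%, and no shift of 100000 reached the observed counts (permutation by shifts, one-sided p = 1e-05 for both, the smallest these shifts can give). Of the optimal peaks, 680 (35.9%) overlapped peaks in both own sets and had a median signal of 132. Another 438 overlapped a peak of replicate 1's set alone, 160 one of replicate 2's alone, and 614 (32.5%), with a median signal of 59.4, overlapped neither set.

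At 1852 optimal peaks both replicates' ranked lists held an overlapping peak. Across these peaks the authors' signal values correlated with a Pearson's r of 0.896 and a Spearman's rho of 0.588 (permutation p = 1e-05 for each, the smallest possible with 100000 permutations, over 2 coefficients). Peaks are not independent replicates. They were selected on the pooled reads of both replicates, which share 1 control, and neither effect on the coefficients was examined. The ratio of replicate 2 to replicate 1 had a median of 0.897 and ran from 0.455 to 1.75 between the 5th and 95th percentiles, and the SD of its log2 was 0.60. Whether the signal scales of the separate lists are comparable is not given in the sources used here. CG14100 had signals of 510.6 and 434.9 in replicates 1 and 2, Ugalt 513.0 and 410.6, and ph-p 332.9 and 333.9.

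Of the 200 optimal peaks of highest signal, 1 had no overlapping place in a replicate's ranked list and could not be compared. Among the others, the 5 with the largest difference in rank share between the replicates were at chinmo, foxo, osp, elav and Boot. The first 4 had the higher signal in replicate 1. The chinmo peak at 2L 1632720 to 1632983, at -18406 bp relative to the nearest start site, had a signal of 152.6 in replicate 1 and 49.5 in replicate 2. The promoter peak of elav, a gene for a neuronal RNA-binding protein, had 140.8 and 57.7. The values were 116.5 and 53.2 for the peak near foxo, a forkhead transcription factor gene, and 124.4 and 55.6 for osp. The Boot peak went the other way, with 69.0 and 108.5. With 2 libraries, a difference at a single peak has no test.

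**Figure D1:**
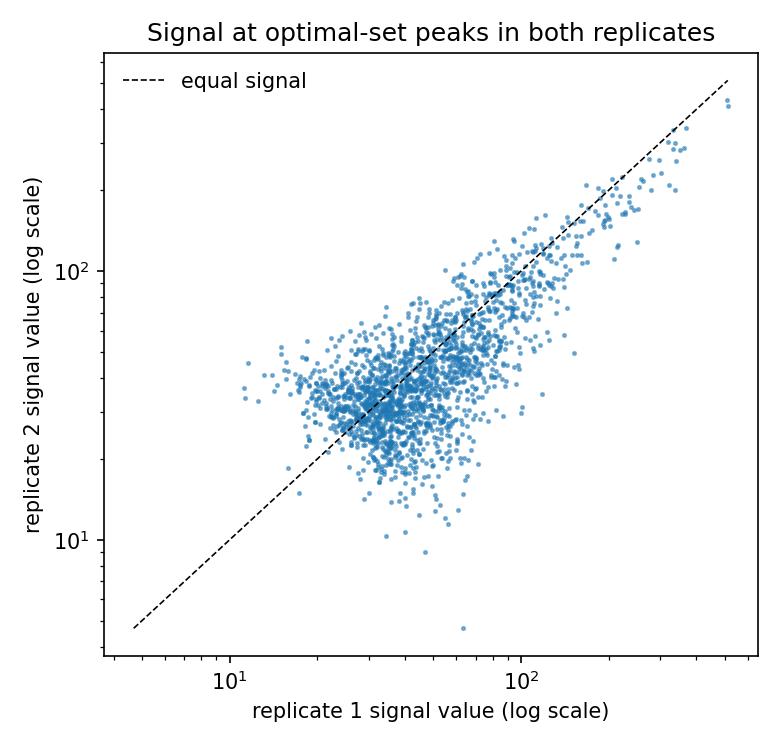
Each point is 1 of 1852 optimal peaks, with the authors' signal value in replicate 1 on the x axis and in replicate 2 on the y axis (no unit, both axes logarithmic); the dashed line marks equal signal. The strongest peaks lie near the line and the weaker ones scatter around it, with a Pearson's r of 0.896 and a Spearman's rho of 0.588.

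The second comparison asked where the optimal peaks lay relative to annotated genes. Promoters held 874 of 1892 summits, or 46.2% (43.9 to 48.5), against 13.6% ± 0.926 (SD over shifts) after circular shifts, 3.40 times as many (permutation by shifts, adjusted p = 3.5e-05). Coding exons held 1.85% against 13.7% after shifts, and 3' untranslated regions 0.793% against 4.41% (same permutation test, adjusted p = 3.5e-05 for each). Intergenic sequence held 14.1% against 27.4% (same permutation test, adjusted p = 3.5e-05), and introns 36.0% against 39.3% (adjusted p = 0.028). The 5' untranslated regions outside promoters (0.476% against 0.778%, adjusted p = 0.198) and other exons (0.581% against 0.814%, adjusted p = 0.34) did not pass the threshold of the permutation test. Promoters held 48.5% of replicate 1's own set (45.6 to 51.3) and 52.0% of replicate 2's (48.6 to 55.4). The intron difference ended when the promoter was taken as 250 bp, with a ratio of 1.00.

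**Figure D2:**
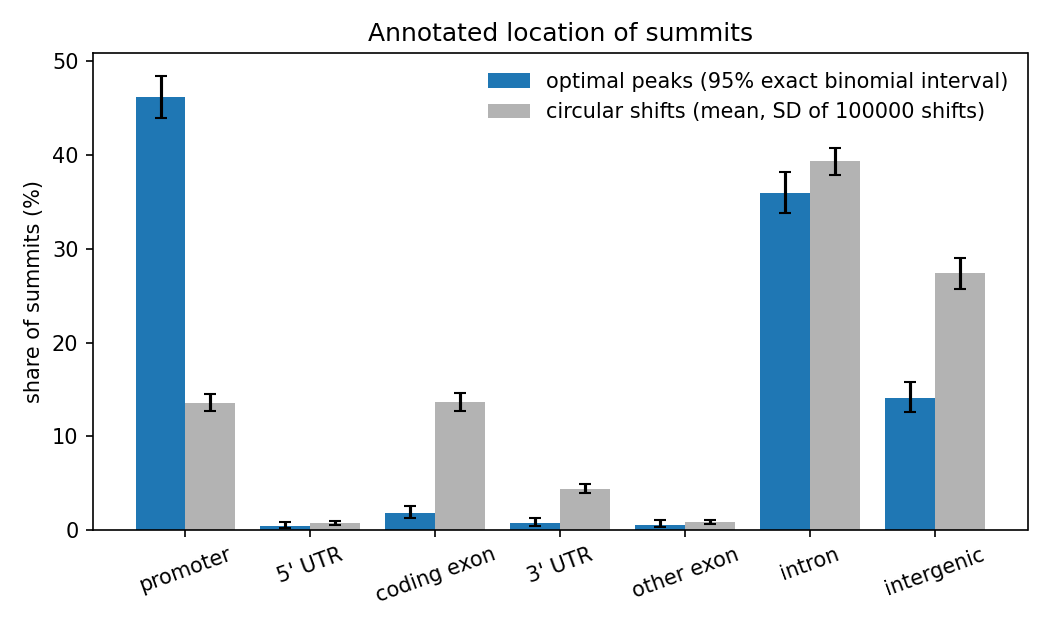
Bars give the share of 1892 optimal summits in each annotated class (y axis, percent), blue for the observed peaks with exact 95% binomial intervals and grey for the mean of 100000 circular shifts with their SD. Promoters hold 46.2% against 13.6%, and coding exons 1.85% against 13.7%.

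Promoter peaks carried the stronger signals. Among the 473 optimal peaks of highest signal 56.4% (51.8 to 61.0) were at promoters, and among the 473 of lowest signal 37.4% (33.0 to 42.0; Fisher's exact test, two-sided p = 6.05e-09). The median distance to the nearest protein-coding start site was 409 bp in the former group and 1290 bp in the latter, and 754 bp over all 1892 peaks. Within 500 bp of such a start site lay 810 summits (42.8%), 643 upstream and 163 downstream, so that 79.4% were upstream (exact binomial test, two-sided p = 3.81e-68), with a median position of -105 bp. A further 376 summits were more than 5000 bp away.

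**Figure D3:**
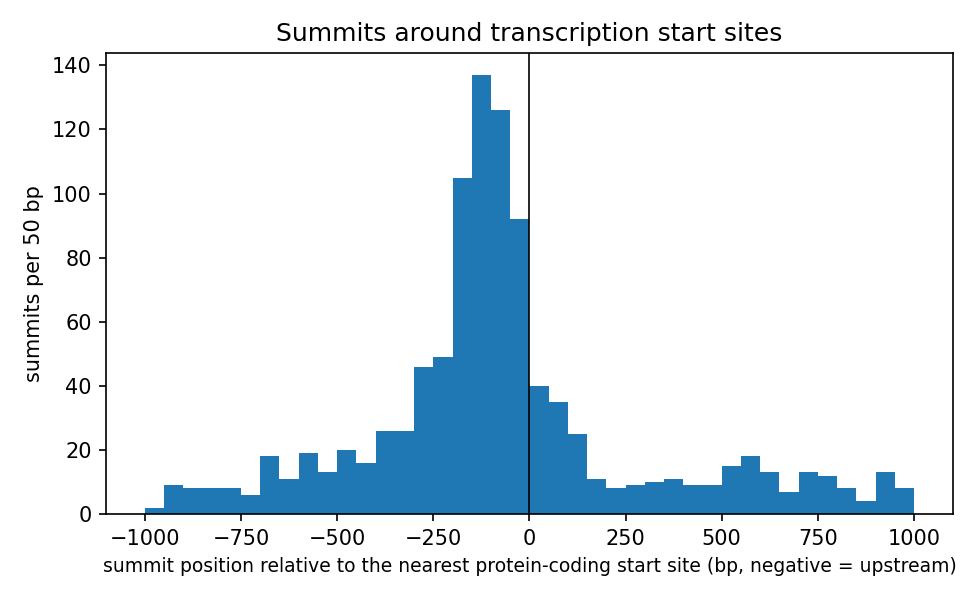
The histogram counts optimal summits per 50 bp (y axis) by their position relative to the nearest protein-coding start site (x axis, bp, negative values upstream). The highest bins lie just upstream of the start site, and 643 of the 810 summits within 500 bp are upstream.

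The third comparison asked whether peaks were spread evenly over the chromosome arms. Chromosome 4, which carries dati and is rich in heterochromatin marks, had 2 optimal peaks, 0.105 times the number its length predicts (0.0127 to 0.379; exact binomial test, adjusted p = 1.46e-05). 1 of them was at the promoter of Sox102F (4 807435 to 807698, signal 67.2). Arm 2L had 382 peaks, 1.15 times the prediction (1.05 to 1.26, exact test, adjusted p = 0.00918). The ratios were 0.949 for 2R, 1.03 for 3L, 0.911 for 3R and 1.05 for X, with adjusted p of 0.419, 0.553, 0.0623 and 0.419. The arm calls depended on the setting: in the same exact test against the number of places per arm in the pooled ranked list, chromosome 4 was at a ratio of 0.835 (adjusted p = 1), 2L at 1.11 (adjusted p = 0.0963) and 3R, now past the threshold, at 0.867 (adjusted p = 0.00417). With 2 peaks, the interval of the chromosome 4 ratio against the pooled places was 0.101 to 3.01, too wide to decide. Against start sites per arm chromosome 4 stayed low in the exact test (0.136, adjusted p = 6.40e-04). There 2R (0.868, adjusted p = 0.00939) and 3L (1.12, adjusted p = 0.0243) also passed the exact test, and 2L did not (1.04, adjusted p = 0.451). In replicate 1's own set alone, which had 5 peaks on chromosome 4, the ratio was 0.413 (exact test, adjusted p = 0.082), and 2L missed the threshold in each replicate's own smaller set at similar ratios (1.12, adjusted p = 0.213 in replicate 2's and 1.10, adjusted p = 0.167 in replicate 1's), while 3R passed in replicate 1's (0.837, adjusted p = 0.00883).

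No peak of any of the 4 thresholded sets lay within dati or 5000 bp of it. The lists without a threshold held weaker places there: the best of 6 in the pooled ranked list was at 4 397381 to 397644, outside the gene, with a signal of 52.4, rank 2331 and an IDR of 0.0228. Replicate 1's ranked list had 13 such places, 8 of them within dati, the best at 400510 to 400759 with a signal of 32.4. Replicate 2's had 1, at 397382 to 397625, with a signal of 36.8. The optimal set had 1.48 peaks per Mb on chromosome 4, so the empty locus carries little weight, and it was not tested.

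The fourth comparison took 16 gene lists fixed before the data were examined and counted the protein-coding genes with a summit within 1000 bp of a start site (called bound genes here). Over the 6 arms 1327 of 13945 genes were bound, or 9.52%. Ribosomal protein genes were bound most often, 46 of 92 (5.25 times the background, odds ratio 9.81, 95% interval 6.35 to 15.2; Fisher's exact test, Benjamini-Hochberg adjusted p = 4.23e-22). Their highest signals were at RpS27 (257.7, 3R 25247483 to 25247554), RpL7 (245.1, 2L 10200987 to 10201074), RpS28b (177.0) and RpL14 (165.3), with summits 12, 14, 23 and 42 bp from a start site. The count was 28 in replicate 1's own set and 33 in replicate 2's.

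In the optimal set, histone genes and chromosome 4 genes were bound less often than the background, and the histone call rested on places left out of that set. Of the genes whose symbol begins with His, 2 of 118 were bound (ratio 0.178, adjusted Fisher p = 0.0105): His2Av, a histone variant gene, and HisRS, which encodes a histidyl-tRNA synthetase and not a histone. The peak at His2Av was nearest to ball, and the summit at HisRS lay 0 bp from the start sites of both HisRS and Bx. Of the chromosome 4 genes 1 of 80 was bound, Sox102F (ratio 0.131, adjusted Fisher p = 0.0335). With the places of the pooled ranked list at the same score or higher that are absent from the optimal set added back, 9 of 118, HisRS included, were bound (ratio 0.783, adjusted Fisher p = 0.732), among them His1:CG33804, His2B:CG33868, His2B:CG33908 and His3:CG33806, while the chromosome 4 call stayed (ratio 0.128, adjusted p = 0.0332). In the 946 peaks of highest signal the ratios were 0.154 and 0, as low as over all peaks, but neither passed the threshold with fewer peaks (adjusted Fisher p = 0.121 each). The histone call was also lost against random lists matched on gene span and start sites (ratio 0.401, adjusted p = 0.427) and within 500 bp of a start site (ratio 0.223, adjusted Fisher p = 0.0671), and the chromosome 4 call within 500 bp (ratio 0.165, adjusted Fisher p = 0.122) and in each replicate's own set (ratio 0 and adjusted p = 0.183 in replicate 2's, 0.387 and 0.543 in replicate 1's). The chromosome 4 call held against the matched lists (ratio 0.0918, permutation, adjusted p = 0.0016) and with gene spans (ratio 0.0901, adjusted Fisher p = 7.31e-04). This call restates the arm result, because its genes share a chromosome with 2 optimal peaks and the tests count them as independent. Of the places in the pooled ranked list 0.124% were on chromosome 4, against 1.01% by length, which the matched lists do not take into account.

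The lists of neural genes did not differ from the background by this rule, but 1 of them did with summits counted anywhere in the gene span or within 1000 bp of it: axon guidance genes, with 9 of 24 (ratio 2.70, adjusted Fisher p = 0.0136). Longer genes have more room for a summit in that count, and lists matched on span were not tested with it. With summits near start sites only, the ratio of axon guidance genes to random lists matched on span and start sites was 1.27 (permutation, adjusted p = 0.903). The ratios to such lists were 0.209 for pan-neuronal, 0.277 for neuroblast and proneural, 0.252 for neuronal identity and 1.56 for glial genes. None of these passed either (permutation, adjusted p from 0.264 to 0.8). Of 26 pan-neuronal genes 1 was bound, elav (signal 195.6, summit 253 bp from a start site; adjusted Fisher p = 0.728). Of 27 neuroblast and proneural genes 1 was bound, brat, a regulator of neural stem cell differentiation (236.0; adjusted Fisher p = 0.728). Of 25 transcription factors of neuronal identity 1 was bound, eg (67.4; adjusted Fisher p = 0.728). Axon guidance genes had 4 of 24 (adjusted Fisher p = 0.56), among them unc-5 (93.8), Ten-a (59.4), Fas3 (59.2) and Sema1a (46.1). Glial genes had 3 of 13 (adjusted Fisher p = 0.319), moody (271.7), which acts in the blood-brain barrier, Gs2 (114.8) and htl (53.5). When each peak was instead given to the nearest start site at any distance, 8 lists passed, among them the transcription factors of neuronal identity (7 of 25, ratio 2.60, adjusted Fisher p = 0.0279) and the Hox genes (5 of 10, ratio 4.64, adjusted p = 0.0122). Against circular shifts under that same rule the ratios were 1.00 and 1.34, with an adjusted permutation p of 1 and 0.976.

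Other lists also missed the threshold. Heat shock genes had 3 of 9 (unadjusted Fisher p = 0.0466, adjusted p = 0.187): Hsp27 (253.7), Hsp83 (161.0) and Hsp26 (58.8). Notch pathway genes had 4 of 16 (adjusted Fisher p = 0.188): numb (151.1), E(spl)mdelta-HLH (95.7, a peak nearest to CG43116), neur (63.6) and N (55.4). Muscle and mesoderm genes had 2 of 19, tin (147.1), a heart and mesoderm regulator, and sls (86.4; adjusted Fisher p = 0.748). Epidermis and trachea genes had 2 of 14, crb (69.7) and rib (46.7; adjusted Fisher p = 0.728). Gut, fat body and hemocyte genes had 1 of 15, ush (76.1; adjusted Fisher p = 1), and sex determination and courtship genes 1 of 9, Sxl (58.7; adjusted p = 0.728). None of 10 Hox genes and cofactors (adjusted Fisher p = 0.728) and none of 19 segmentation genes (adjusted p = 0.56) was bound. In simulations with a list of 26 genes a bound share of 25% was called in 30 of 100 runs and a share of 50% in 98.

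**Figure D4:**
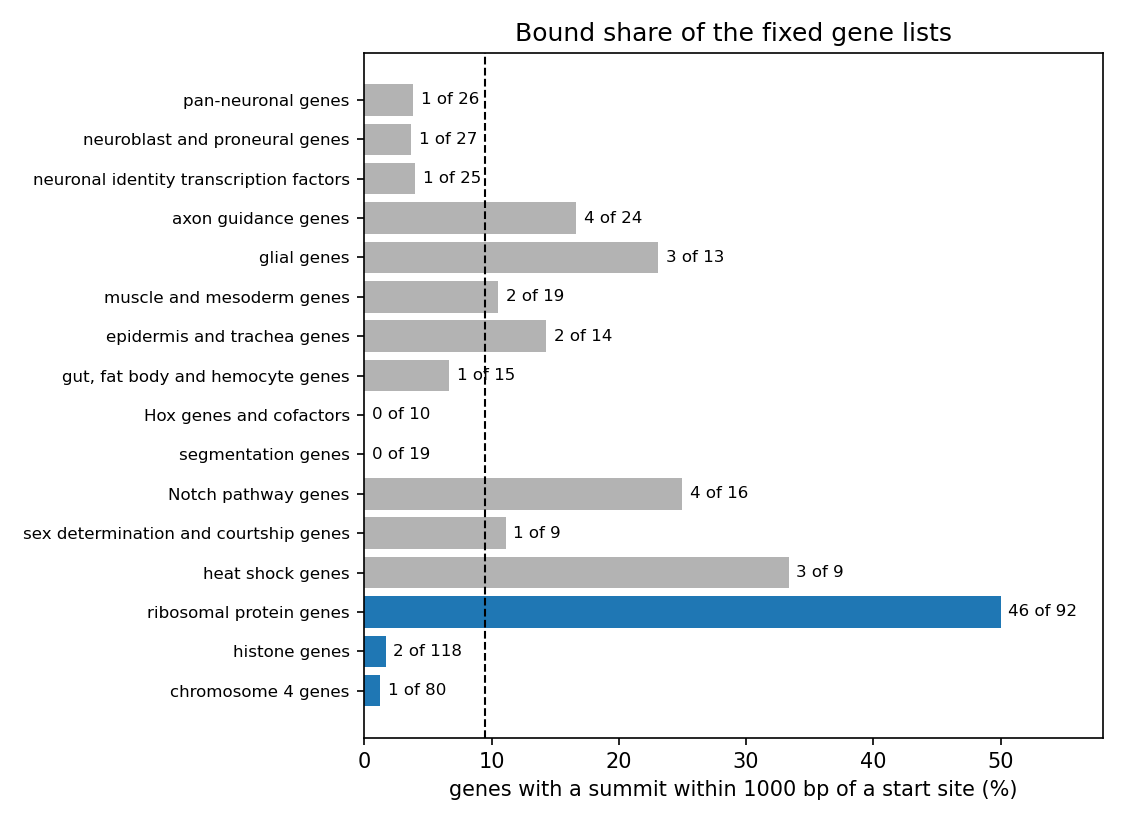
Bars give the share of each fixed list's genes with an optimal summit within 1000 bp of a start site (x axis, percent), blue where the adjusted p is below 0.05 and grey otherwise; the dashed line is the background of 9.52%. Ribosomal protein genes reach 46 of 92, while histone and chromosome 4 genes lie below the line.

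The fifth comparison looked at the sequence under the summits. Windows reaching 50 bp to each side of optimal summits had a mean GC content of 36.3%, and windows of the same size centred 500 bp away 42.8%, a difference of -6.48 ± 12.9 percentage points (SD over 1892 peaks). The difference followed the signal: it was -10.8 percentage points in the 473 peaks of highest signal and -0.699 in the 473 of lowest signal. Of 16 motifs fixed beforehand, 7 differed from the flanks by Fisher's exact test. The M1BP motif GGTCACAC, a core promoter element of housekeeping genes, was in 0.899% of summit windows and 0.132% of flanks (ratio 6.80, adjusted Fisher p = 1.60e-04), and the DREF element TATCGATA in 1.16% and 0.344% (ratio 3.38, adjusted p = 0.00137). The homeodomain core TAATTA was in 8.93% and 6.18% (adjusted Fisher p = 7.52e-04).

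The GAGA repeat was in 0.740% of summit windows and 2.93% of flanks (adjusted Fisher p = 2.02e-07), the CA repeat in 1.37% and 3.46% (adjusted p = 2.18e-05), and the E-boxes CACCTG (2.91% and 4.52%, adjusted p = 0.0071) and CAGCTG (3.49% and 5.44%, adjusted p = 0.00257) were also rarer at summits. None of the 7 held against windows matched on GC content and distance to a start site: 0 of the 16 motifs passed Fisher's exact test there, with a smallest unadjusted p of 0.0513, for the GATA factor site, and 0 at an unadjusted p below 0.05. In replicate 1's own set the M1BP and DREF calls were already lost against the flanks (adjusted Fisher p = 0.273 and 0.0902), and in replicate 2's own set those of TAATTA, CACCTG and CAGCTG (0.0525, 0.0729 and 0.128).

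A scan of all 2080 6-mers found 436 on 2L, 2R, X and 4, and 233 of these differed again on 3L and 3R, 139 of them higher at summits. Of the 139, 90.6% consisted of A or T in at least 5 of 6 positions, and the first, TTAAAA, was in 32.0% of summit windows on 3L and 3R and 14.6% of flanks. Against the matched windows 14 were found and 2 differed again, both higher at summits. These were ACAGTG, in 8.04% and 3.53% of windows on 3L and 3R (adjusted Fisher p = 4.55e-05), and CAGTGC, in 6.70% and 3.35% (adjusted p = 0.0018), which share 5 bases.

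**Figure D5:**
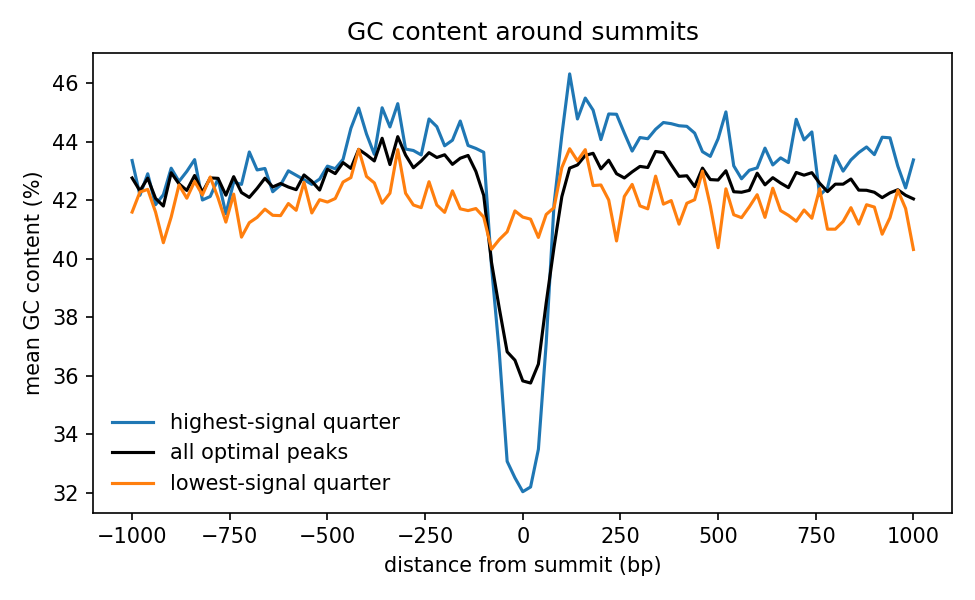
Lines give the mean GC content (y axis, percent, not starting at 0) by distance from the summit (x axis, bp) for all 1892 optimal peaks and for the 473 of highest and of lowest signal. GC content falls around the summit in the peaks of highest signal and stays near the level of the flanks in those of lowest signal.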

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

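In this part, the return of absent places to the gene lists was chosen after the values were seen. The pooled ranked list held 89 places at the score of the optimal set or higher that are absent from the set, and the comparisons of the report use them only where they were added back. Of these 61 were on the 6 arms, 28 of them on 3R and 19 on 2L, and 5 were among the 50 highest of the list. They include an intron of cbt (2L 480990 to 481203, signal 765.0), an intron of Lk6 (3R 11760956 to 11761119, 562.4), the promoter of larp (405.8), an intron of trx (355.2) and the promoter of RpL13A (125.2). Another 4 had a histone gene as the nearest: His1:CG33804 (2L 21426558 to 21426821, signal 83.8), His2B:CG33868 (74.5), His2B:CG33908 (72.0) and His3:CG33806 (67.0). Adding the places on the 6 arms back raised the bound genes of the histone list, HisRS included, from 2 to 9 of 118 (without it, from 1 to 8) and ended that list's call (ratio 0.178 before and 0.783 after, adjusted Fisher p = 0.0105 and 0.732). Why they are absent was not tested.

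Outside the 6 arms the optimal set held 23 peaks on 22 scaffolds labelled as X, with a highest signal of 300.2. They were left out of the tests, which covered the 6 arms.

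Replicate 1's ranked list held 543 places on chromosome 4 among 107484 (0.505%), and replicate 2's held 82 among 122195 (0.0671%). With 1 list per replicate the difference has no test. Chromosome 4 makes up 1.01% of the length of the 6 arms, so both lists fell short of it.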

How the results depend on the processing

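The alternatives gave 397 values for single classes except promoters, for arms, lists and motifs, and for Pearson's r. The same side of the threshold was kept by 350, 38 of them crossing a ratio of 1 without a call in either setting. Another 31 lost a call and 16 gained one. Of these, 4 that lost and 2 that gained a call also crossed a ratio of 1, and none was called in opposite directions. The 350 include repeats of the report's own values, because removing HisRS alters the histone list alone and merging overlapping peaks changed no list's count. They are therefore not 350 independent checks. Overlap, signal correlation and promoter share kept their calls under every alternative run. The promoter ratio ran from 2.46 to 4.64 and that of ribosomal protein genes from 3.84 to 7.21. The dati locus stayed empty in every set tried, a count without a test, and subsets of the optimal set could only repeat it. There were 2 alternatives chosen after seeing the data: removing HisRS from the histone list, which left that call in place, and adding back the places absent from the optimal set, which ended it (ratio 0.783).

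The number of arms past the threshold, 2 in the report, was 3 in the conservative set, with overlapping peaks merged and against start sites per arm. It was 1 in the 946 peaks of highest signal, 1 against places of the pooled ranked list, and 1 without replicate 1 or without replicate 2. Arm 3R was newly lower in the conservative set (0.896), with merged peaks (0.907), without replicate 2 (0.837) and against the pooled places (0.867). The number of gene lists, 3 in the report, was 2 without replicate 1, without replicate 2, against matched lists and with the absent places added back. It was 4 with gene spans, where axon guidance genes joined (ratio 2.70), 1 in the 946 peaks, 1 within 500 bp of a start site and 8 under the nearest start site, where the ratio of neuronal identity transcription factors went from 0.420 to 2.60 and that of Hox genes from 0 to 4.64. The number of motifs, 7 in the report, ran from 4 to 6 without either replicate, was 6 in windows of 51 bp and 0 with matched windows, where CACCTG went to a ratio of 1.07, CAGCTG to 1.14 and TAATTA to 0.955. The 233 6-mers became 112 to 280 without either replicate, 231 in the conservative set, 247 in the 946 peaks, 224 with merged peaks, 72 in windows of 51 bp, 333 in the widest windows and 2 with matched windows. The number of location classes, 5 in the report, was 6 with local shifts, where 5' untranslated regions joined (ratio 0.493), and 4 with promoters of 250 bp, where the intron ratio went from 0.915 to 1.00. The histone call ended with the absent places because 7 more histone genes have a start site near them. The matched windows remove differences of GC content and of the class of distance to a start site by construction, and each replicate's own set holds fewer peaks. The cause of the other changes was not tested, except for the nearest start site, which is weighed among the other observations. The depth of the libraries is unknown and its effect on the number of weak peaks was not examined.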

Other observations

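The tests in this part were chosen after the results of the report were seen, except the matched random lists, which were planned. The outcome each explanation needed was set down before its test was run, except for those lists.

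Families of genes defined by the letters of their symbols gave a wider view of what was bound. Of 40 families with at least 15 genes, 6 differed from the background by Fisher's exact test with Benjamini-Hochberg adjustment. Besides the ribosomal proteins, the family pre was higher, with 10 of 24 (adjusted Fisher p = 6.63e-04), but all 10 are pre-mod(mdg4) entries behind 1 peak at 3R 21365259 to 21365522 (signal 77.5), so it is a single place. Cuticle protein genes of the Cpr family had 0 of 70 bound (odds ratio at most 0.512, adjusted Fisher p = 0.0162), gustatory receptor genes (Gr) 0 of 60 and ionotropic receptor genes (Ir) 0 of 60 (odds ratio at most 0.601, adjusted Fisher p = 0.0407 each). In the histone family His2Av alone was bound in the optimal set (ratio 0.0914, adjusted Fisher p = 0.00404), but with the absent places added back 8 genes were (ratio 0.714, unadjusted Fisher p = 0.428), so this low count rests on the places left out of the set. The next families missed the threshold: PIG genes had 5 of 21 (ratio 2.50, adjusted Fisher p = 0.248) and vacuolar ATPase genes (Vha) 5 of 22 (ratio 2.39, adjusted p = 0.26). Mitochondrial ribosomal protein genes had 10 of 73 (ratio 1.44, adjusted Fisher p = 0.478) and translation initiation factor genes (eIF) 6 of 44 (ratio 1.43, adjusted p = 0.557). Neighbouring genes of a cluster are not independent, which these tests do not take into account. The Cpr, Gr and Ir families were also not matched on gene span or number of start sites. The histone list lost its low call under such matching (ratio 0.401, permutation, adjusted p = 0.427). The low counts of these 3 families therefore cannot be separated from those gene traits.

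Promoter summits often had start sites on both strands. Of 810 summits within 500 bp of a protein-coding start site, 250 (30.9%) had start sites on both strands within that distance, against 10.9% ± 2.14 (SD) of the promoter summits of 2000 circular shifts (permutation p = 0.001, the smallest these shifts can give). The shifts do not keep the mostly upstream position of the observed summits, and how much of the excess follows from it was not tested. At the 46 bound ribosomal protein genes the median summit lay at -22.5 bp from the start site (quartiles -43.5 and -9.25), and at the other 1281 bound genes at -146 bp (-303 and -47). The log2 ratio of replicate 2 to replicate 1 was 0.20 ± 0.53 (SD) at 44 ribosomal protein peaks and -0.20 ± 0.61 at 809 other peaks within 500 bp of a start site (permutation across peaks, p = 5e-05), which compares these 2 libraries only. The 6-mer ACAGTG was in 7.98% of all 1892 summit windows and 4.02% of matched windows, with 8.01% at promoters and 7.96% elsewhere, and with 6.98%, 7.40%, 9.51% and 8.03% from the 473 peaks of highest signal to the 473 of lowest.

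Ribosomal protein genes were bound 5.25 times as often as the background. Gene span and the number of start sites do not account for it, since the ratio to random lists matched on both was 4.43 (permutation p = 2e-04, the smallest these lists can give). Signal at highly transcribed genes in general, specific or not, stays open, and the outcome it needed was met at protein-coding genes. Of 24 other genes listed as highly transcribed from general knowledge 8 (33.3%) were bound, among them Act5C, eEF1alpha1 and alphaTub84B (ratio 3.50, Fisher p = 0.0012). That share did not differ from that of the ribosomal protein genes by Fisher's exact test (p = 0.172). With 24 genes a difference could be missed, and this list was not matched on gene span or start sites. Its bound genes include the translation factor genes eEF1alpha1 and eEF1gamma, so it does not separate high output from translation genes. At tRNA genes the ratio to shifted peaks was 2.27 (9 of 290 genes, permutation p = 0.11), too few to decide. Expression was not measured here and the design has no second condition, so no biological explanation was tested.

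The low GC content at summits may have technical or sequence sources. Promoter composition is not the whole cause, because summits farther than 1000 bp from any start site also differed from their flanks, by -4.34 percentage points (95% interval -5.20 to -3.48, 791 peaks), against -8.55 within 500 bp. A bias of the libraries toward AT-rich sequence at all enriched places was not decided. Weak peaks from far down the pooled ranked list were richer in GC than their flanks by 4.23 percentage points (4.01 to 4.44, 9945 peaks). Only 4064 of the 156658 places in that list had an IDR of 0.05 or less, so these weak peaks may be mostly unenriched. Among the optimal peaks, the difference in the 473 of lowest signal was -0.699 percentage points. A preference of the fusion protein for AT-rich sites and a tendency of strong peaks to lie in open chromatin remain open and were not tested.

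When each peak was given to the nearest start site, the lists of neuronal identity, axon guidance, glial, muscle and Hox genes passed the threshold. A candidate explanation is that these genes have large surroundings that catch more peaks under this rule. Circular shifts of the same peaks gave a mean of 22.5 bound genes over the 91 genes of the 5 lists, and 30 were observed, a ratio of 1.33 (permutation p = 0.079). The shifts thus reach most of the count, and the excess did not pass the test. For single lists the ratios to the shifts were 1.00 for neuronal identity, 1.03 for axon guidance, 1.34 for Hox, 1.85 for muscle and 2.81 for glial genes (adjusted permutation p from 0.208 to 1), while ribosomal protein genes stayed at 7.59 (adjusted permutation p = 0.0032). Histone genes, called low under this rule, were at 0.367 against the shifts (unadjusted permutation p = 0.71). For chromosome 4 genes, also called low, every shift within the arm gave 2 bound genes, so the shifts cannot test that list.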
